A study of Arabidopsis thaliana with 6 samples.

How the data were processed

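RNA from roots of Arabidopsis seedlings was measured on 6 one-colour NimbleGen arrays, 3 from a pER8::GFP line and 3 from a pER8::OBP4 line. In both lines the transgene is switched on by estradiol, and the GFP line serves as the control. Per the labels' protocols, 5-day-old seedlings were moved to medium with 10 µM estradiol for 8 h, grown under 16 h of light, and 10 µg of root RNA was copied to cDNA and labelled with Cy3. Per the labels, each replicate came from its own culture plates.

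The authors deposited 1 table per array with a log2 value for each of 37118 gene models, each from the probes for that model, 59 of them from 1 probe only. RMA, which corrects background, normalizes between arrays and summarises probes, is named by the deposited tables' own titles. The software, its version and its settings are not given in the sources used here. The deposited log2 values ran to just under 16, the ceiling of a 16-bit scanner, so differences among very bright genes are compressed. Of 1204 loci with a mean of 15.5 or more, 3 passed the test, and of 9769 loci with a mean under 8, 378 did. A second deposited table of log2 values for the same sample names, with its normalization not stated, was used as an alternative source. Its values did not follow the arrays (see the closing part on results for a closer look), so no main result rests on it. No per-sample column was left unused.

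Gene models of a locus were averaged on the log2 scale, which gave 32627 loci, 3602 of them with more than 1 model. Symbols came from the NCBI reference table of the TAIR10.1 assembly, which held 31993 of the loci (98.1%), and otherwise from the array annotation. Coordinates are those of the array annotation, whose genome build is not given in the sources used here. No further normalization and no filter on dim genes was applied in the main analysis.

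OBP4 and control arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all loci and a threshold of 0.05. The labels' protocols state no test. Differences are OBP4 minus control on the log2 scale, with the standard error of the limma fit, and group values are means with the SD of 3 arrays. No depth applies to arrays, and 3 arrays per group limit the precision. No 2 arrays held identical values.

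Before the data were examined, 27 gene lists (540 entries, 530 loci) and the rule for named genes were fixed. Of the entries, 501 had the same symbol and locus in the reference, 38 symbols were absent from it and their locus was used, and 1, COG1, was placed by the reference at another locus, AT3G44480, which was used by the fixed rule although that locus is RPP1 and not a DOF gene. Each list was tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists, and beside it with camera with an estimated correlation and with fry. Camera compares a list with all other loci, while fry asks whether its genes move, on balance, one way. Genes named in the text are OBP4, the 10 largest increases and 10 largest decreases among loci past the threshold with a symbol and no overlap between the groups' arrays, and up to 3 members past the threshold per list by size of change (up to 6 for root hair, DNA replication, mitosis, and callus and regeneration). RSL2 and RSL4 were named regardless of their p. Other genes are named where a count is small or where they were chosen after their values were seen, as the text then says.

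The limma fit was tested on simulated data for the 32627 loci, with the spread of each locus taken from the arrays. It recovered 4 of 67 loci changed by 0.5 (log2), 31 of 67 changed by 1 and 52 of 66 changed by 2, with 0 calls among unchanged loci. The simulation changed far fewer loci than passed in the arrays, which makes its adjusted threshold stricter, so these shares are not those of the real comparison. Its noise was drawn independently for each locus, without any correlation between genes. The 0 calls therefore do not measure how often unchanged loci are called in the real arrays.

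Alternatives tried were quantile normalization again, centring each array on its median, cyclic loess, the second table as source, leaving out the dimmest 25% or 50% of loci, eBayes with trend and robust settings, array weights, the replicate number as a block, the brightest row per locus, a stricter adjusted p of 0.01 or a minimum change of 1, the other set tests, and leaving out each array in turn. The mean of the photosynthesis list as a covariate, and AT1G29160 as the locus of COG1, were added after the data were seen. Figures were drawn with matplotlib in Python.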

Results

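Transcript levels were measured in roots of 2 Arabidopsis lines after 8 h of 10 µM estradiol, with 3 arrays from pER8::OBP4 roots and 3 from pER8::GFP control roots. OBP4 is a transcription factor of the DOF family, plant proteins with a single zinc finger that binds DNA. The comparison asks which root transcripts differ between the OBP4 and control lines after estradiol, in a study concerned with root growth, cell elongation and callus. Both lines received estradiol, and arrays without it were not analysed here. Differences between the lines that precede induction are therefore not separated from effects of OBP4 overexpression, at any locus named below. Array medians lay between 11.83 and 11.89 on the log2 scale. Correlations across loci were 0.982 to 0.995 within a group and 0.970 to 0.985 between groups, and the first principal component, with 50.5% of the variance, separated the groups. The second component, with 23.0%, placed OBP4 replicate 1 at -54.8 and OBP4 replicate 2 at 57.4.

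OBP4 transcript was higher in every pER8::OBP4 array than in every control array. OBP4 (AT5G60850; chromosome 5, 24480449 to 24481873, forward strand, on the coordinates of the array annotation) stood at 15.81 ± 0.07 (SD, n = 3) in OBP4 roots and 14.54 ± 0.21 (SD, n = 3) in control roots. The difference was 1.27 ± 0.12 (SE) on the log2 scale, or 2.41-fold, with limma's adjusted p = 0.00279. Values near 16 are at the top of the scanner's range, so the fold is compressed, and the probes do not tell the transgene from the endogenous gene.

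Of 32627 loci, 1705 were higher and 2767 lower in OBP4 roots by limma with adjusted p under 0.05, so that 61.9% of the 4472 changed loci were lower. By at least 1 on the log2 scale, 560 rose and 999 fell. The strongest increases with a symbol were in LCR25 (7.22 ± 0.23, SE) and LCR26 (4.40), which encode small cysteine-rich proteins, ORP4C (5.71), an oxysterol-binding protein homologue, and IDL3 (5.35), a relative of the abscission peptide IDA. PP2-B13 (4.86), a phloem protein-like gene, WOX4 (4.86), a homeobox gene of the vascular cambium, and GPAT1 (4.37), a glycerol-3-phosphate acyltransferase, followed. WRKY71 rose by 4.22, BGLU27 by 4.19 and CYP71B5 by 4.17. LCR25 (14436284 to 14436631) and LCR26 (14432741 to 14433084) lie close together on the reverse strand of chromosome 4. Whether their increases are separate responses was not tested. The strongest decrease with a symbol was in QQS (-4.67 ± 0.16, SE), an orphan gene linked to starch levels. CYP82C4 (-3.89) and its relative CYP82C2 (-2.81), NRT2:1 (-3.65), a high-affinity nitrate transporter, IRT3 (-3.37), a metal transporter, and FRO2 (-2.89), the ferric chelate reductase of the root surface, fell too. So did CER4 (-2.99), a fatty acyl reductase, DES-1-LIKE (-2.79), MEE39 (-2.73) and EXPA17 (-2.67), an expansin. Of these genes, LCR25, LCR26, IDL3, PP2-B13, ORP4C and CYP71B5 had control means of 5.89 to 7.78, and QQS (7.41) and DES-1-LIKE (7.85) were as dim in OBP4 roots, so the sizes and order of these changes are less exact. Groups did not overlap at 12027 loci (36.9%), against 10% by chance. Without single arrays the count of higher loci was 963 (control replicate 1), 1050 (control 2), 892 (control 3), 968 (OBP4 replicate 2) and 1029 (OBP4 3), and that of lower loci 1705 (control 1), 1571 (control 3) and 1732 (OBP4 2). With the replicate number as a block, 588 loci were higher and 1114 lower.

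**Figure D1:**
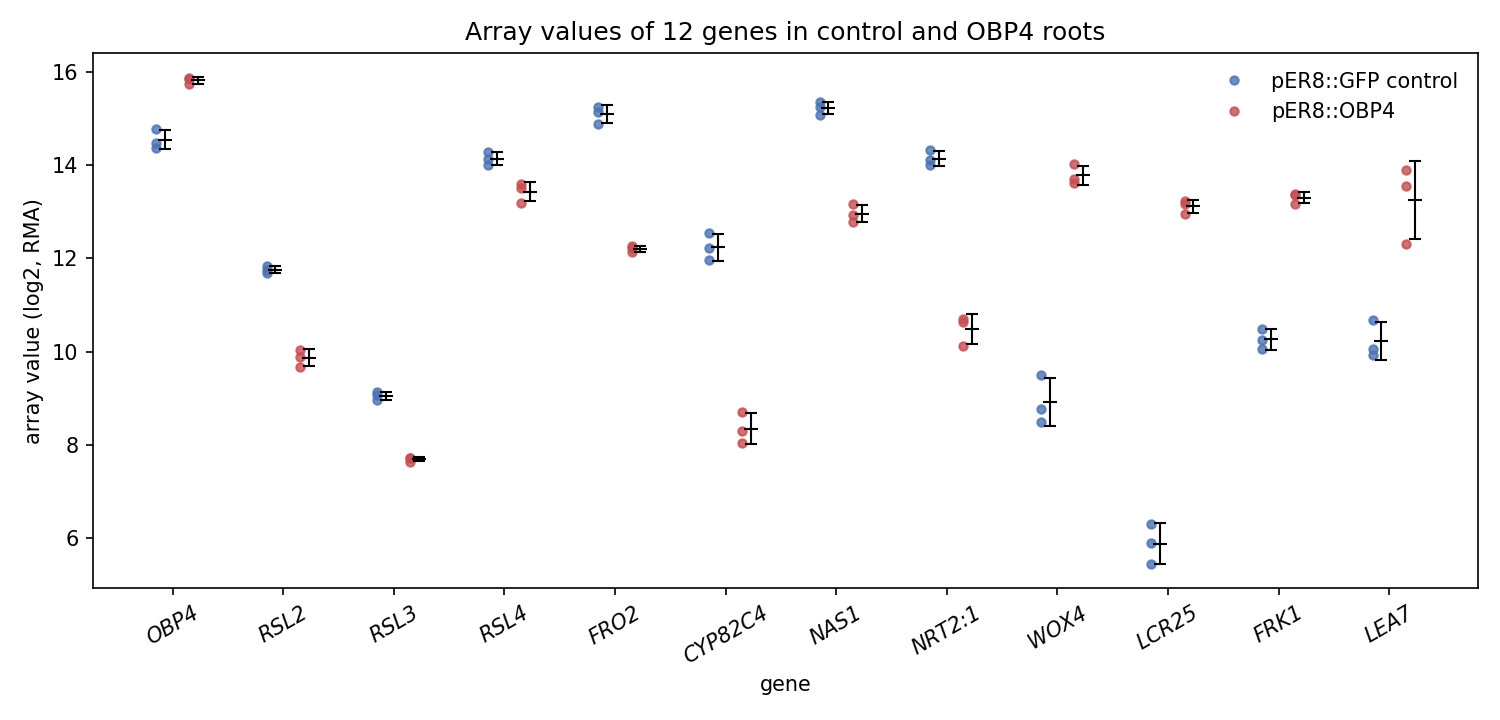
Array values on the log2 scale (vertical axis) of 12 genes (horizontal axis) in 3 control arrays (blue points) and 3 OBP4 arrays (red points), with the mean and SD of each group as black bars. For each gene the 3 OBP4 arrays lie on one side of the 3 control arrays: OBP4 at 15.81 against 14.54, RSL2 at 9.87 against 11.75, and LCR25 at 13.11 against 5.89.

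Root hair genes fell together in OBP4 roots. Of 34 measured genes of the root hair list, which holds regulators and wall and signalling genes of these tubular outgrowths of the epidermis, 22 fell, 12 did not pass the test and 0 rose; adjusted over the list alone, 27 fell. The bHLH transcription factors RSL2 (-1.89 ± 0.11, SE), RSL3 (-1.35) and RSL4 (-0.71 ± 0.14) fell, as did GEF3 (-1.54), an activator of ROP GTPases, the phosphatidylinositol phosphate kinase gene PIP5K3 (-1.33), RHS12 (-1.29) and the kinase gene IRE (-1.29). RSL3 was dim in OBP4 roots (7.70), so the size of its change is less exact. RSL2 went from 11.75 ± 0.07 to 9.87 ± 0.18 (SD, n = 3), with adjusted p = 0.00071, and RSL4 from 14.14 ± 0.15 to 13.43 ± 0.21 (SD, n = 3), with adjusted p = 0.0285; RSL4 passed in 1 of the 6 fits without 1 array. The list median was -0.69, and camera gave adjusted p = 5.36e-15. With the correlation estimated from the arrays, 0.46 against the preset 0.01, camera gave adjusted p = 0.703. Fry gave adjusted p = 0.00755. Without control replicate 1, 13 members fell. Among 12 genes that pattern the root epidermis, GL2 (-0.74), MYB23 (-0.71) and WER (-0.53), which set the non-hair fate, fell and MYC1 (0.70) rose, with adjusted p = 0.0535 by camera and 0.0428 by fry; adjusted over the list alone, 5 fell and 1 rose. Of the 6 fits without 1 array, GL2 and MYC1 passed in 2 and MYB23 in 1.

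Iron uptake genes fell. Of 22 measured genes of the iron deficiency response, 12 fell, 1 rose and 9 did not pass; adjusted over the list alone, 13 fell and 3 rose. CYP82C4 fell from 12.24 ± 0.29 to 8.35 ± 0.33 (SD, n = 3), FRO2 from 15.09 ± 0.19 to 12.21 ± 0.07 and the nicotianamine synthase gene NAS1 from 15.22 ± 0.13 to 12.96 ± 0.19, with adjusted p of 0.00069, 0.000414 and 0.000618. Another nicotianamine synthase gene, NAS4, rose by 1.35. Camera gave adjusted p = 2.95e-05 for the list, with adjusted p = 0.703 with an estimated correlation and 0.00344 by fry.

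Abscisic acid genes rose in part, and more cytokinin genes fell than rose. Of 27 measured abscisic acid genes, 8 rose and 0 fell; adjusted over the list alone, 13 rose and 1 fell. LEA7, a late embryogenesis abundant protein gene, rose by 3.02 ± 0.46 (SE), the phosphatase gene HAI2 by 1.84 ± 0.38, and NCED3, an enzyme of abscisic acid synthesis, by 1.19 ± 0.17. The list's camera adjusted p = 5.38e-04, its adjusted p = 0.737 with an estimated correlation, and fry's was 0.0211. The number of higher members was 5 without control replicate 2, 3 without control 3, 5 without OBP4 replicate 1 and 4 without OBP4 2. It was 5 with the photosynthesis mean as a covariate and 4 with the replicate block. In the second deposited table it was 0, and the list mean reversed to -0.26. Of 24 cytokinin genes, 5 fell and 1 rose; adjusted over the list alone, 11 fell and 3 rose. CKX7 (2.21) rose, and CKX4 (-1.86) fell; both encode cytokinin oxidases, which break the hormone down. CYP735A1 (-0.71), which makes trans-zeatin types of the hormone, fell too. Camera gave the cytokinin list adjusted p = 0.00776, with adjusted p = 0.703 with an estimated correlation and 0.0617 without the dimmest 50% of loci. Fry gave that list adjusted p = 0.0134. HAI2 and CYP735A1 each passed in 1 of the 6 fits without 1 array.

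Auxin, jasmonate and salicylate genes went both ways, and none of these lists passed camera. Of 22 auxin genes 3 rose, IAA5 (2.11) and the kinase gene PID (1.02) among them, and 2 fell, GH3.2 (-0.99; past the threshold in 0 of the 6 fits without 1 array) among them; adjusted over the list alone, 4 rose and 2 fell. All 5 PIN auxin efflux carrier genes stayed short of the threshold, with a list median of 0.04. Of 21 jasmonate genes, LOX4 (3.35), a lipoxygenase gene, rose and 3 fell, ORA59 (-1.63) and JAZ6 (-0.79) among them. ORA59 was dim in OBP4 roots (7.12), so the size of its change is less exact. Adjusted over the jasmonate list alone, 3 rose and 3 fell. Among 19 salicylate and immune genes 6 rose and 2 fell, and adjusted over the list alone 7 rose and 2 fell. The receptor kinase gene FRK1 (3.04), WRKY53 (from 10.93 ± 0.12 to 13.13 ± 0.15, SD, n = 3) and WRKY40 (2.06) led the increases. The adjusted p of these lists by camera was 0.631 for auxin, 0.901 for PIN, 0.631 for jasmonate and 0.319 for salicylate, which fry called as higher with adjusted p = 0.00978. JAZ6 and WRKY40 each passed in 2 of the 6 fits without 1 array.

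Few cell division genes passed the test. None of 31 measured DNA replication genes passed the test by limma, with a median of 0.01 on the log2 scale, and adjusted over the list alone 0 rose and 0 fell. Of 29 mitosis genes, the A-type cyclin gene CYCA2;3 rose by 0.54 ± 0.11 (SE), and 28 did not pass; adjusted over the list alone 0 rose and 0 fell, and CYCA2;3 passed in 2 of the 6 fits without 1 array. Of 10 D-type cyclin genes, CYCD5;1 fell by 0.49, and adjusted over the list alone 2 rose and 2 fell. Inhibitors and endocycle genes went both ways: of 20, the inhibitor gene KRP5 (1.05) and SMR8 (0.68) rose and 3 fell, SMR3 (-0.67) among them, with the same counts adjusted over the list alone. Of 31 callus and regeneration genes, 6 rose and 1 fell (adjusted over the list alone, 7 and 2). The homeobox gene WOX11 rose from 10.24 ± 0.18 to 11.73 ± 0.14 (SD, n = 3), LBD17 by 0.76, PLT5 and ARF19 each by 0.51, and WOX13 by 0.41, while WOX12 fell by 0.94. Camera's adjusted p was 0.901 for DNA replication, 0.716 for mitosis, 0.901 for D-type cyclins, 0.608 for inhibitors and 0.609 for callus and regeneration, which fry called as higher with adjusted p = 0.0457. ARF19 passed in 2 of the 6 fits without 1 array, and PLT5 and WOX13 in 1. The medians of the callus, mitosis and D-type cyclin lists (0.02, -0.01 and -0.01) lay so close to 0 that their sign turned with the scaling of all loci, and no direction is read from them.

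Wall and water transport genes changed in part. Of 28 expansin genes, 2 rose and 4 fell, with EXPA17 (-2.67), EXLA2 (-1.08) and EXLA3 (1.26) moving furthest; adjusted over the list alone, 3 rose and 5 fell. Of 30 xyloglucan endotransglucosylase genes, 4 rose and 9 fell, led by XTH11 (2.99), XTH29 (1.81) and XTH17 (-1.39). XTH29 was dim in control roots (7.65), so the size and rank of its change are less exact. Adjusted over the list alone, 6 rose and 13 fell. The mean of this list was 0.05 and its median -0.07, so that they differ in sign, and camera pointed down with adjusted p = 0.334; for expansins adjusted p = 0.716. Of 19 aquaporin genes, 5 fell and 0 rose (adjusted over the list alone, 7 and 0): PIP2;4 fell by 0.61, PIP1;4 by 0.58 and TIP2;3 by 0.52. PIP2;4 and TIP2;3 had control means of 15.57 and 15.69, near the scanner's ceiling, so their changes are compressed. Camera gave aquaporins adjusted p = 0.0187, with adjusted p = 0.737 with an estimated correlation. Without control replicate 1 camera's adjusted p was 0.0704, and fry's with all arrays was 0.0211. Of the 6 fits without 1 array, EXLA2 passed in 2, and XTH29, PIP2;4 and PIP1;4 each in 1.

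Other DOF genes changed in OBP4 roots too. Of 27 measured entries, 7 rose and 3 fell (the same adjusted over the list alone). The entries include RPP1, which the fixed rule used for COG1 and which is not a DOF gene. These counts were not retaken with the other locus of COG1. CDF1 (2.47 ± 0.09, SE), CDF4 (1.68) and CDF5 (1.67), of the cycling DOF factors, rose. CDF5 was dim in control roots (6.90), so the size of its change is less exact. The list had adjusted p = 0.631 by camera and 0.00978 by fry, which called it higher. Of 18 clock genes CCA1 (1.27) and COR27 (1.11) rose among 3, and PRR9 (-0.91) fell among 2; adjusted over the list alone, 4 rose and 6 fell. The clock list had a median of -0.12 and a mean of 0.02, with camera pointing down and adjusted p = 0.716. Of 16 glutathione transferase genes 3 rose, with GSTU4 (2.02) and GSTU3 (1.19), and GSTU22 fell from 15.38 ± 0.05 to 14.38 ± 0.06 (SD, n = 3); adjusted p = 0.45. Of 25 endodermis and suberin genes, MYB41 (1.52) and GPAT7 (0.63) rose and CASP4 (-0.62) fell, with adjusted p = 0.619; adjusted over the list alone the counts of both lists were unchanged.

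No xylem, phloem or reference gene of the lists passed the test, and root cap genes fell in part. None of 12 xylem and secondary wall genes (median -0.05) and none of 8 phloem genes (median -0.05) passed by limma, also adjusted over the list alone, with camera's adjusted p of 0.45 and 0.619. Of 4 root cap genes, the NAC genes BRN1 (-1.29 ± 0.13, SE) and BRN2 (-0.65 ± 0.08) fell, adjusted over the list alone too. Fry gave the root cap adjusted p = 0.0228. Camera gave it adjusted p = 0.0435, and adjusted p = 0.737 with an estimated correlation. Camera's call was lost without control replicate 3 (0.115), OBP4 replicate 1 (0.0792) or OBP4 3 (0.0763). It was also lost under quantile normalization (0.0511), without the dimmest 25% of loci (0.0705), with the replicate block (0.0552) and with the photosynthesis covariate (0.0677). Of 9 heat shock genes, HSP90.1 (0.68) and HSP70 (0.46) rose, adjusted over the list alone too, with camera's adjusted p = 0.0187 and adjusted p = 0.799 with an estimated correlation. Of the 6 fits without 1 array, HSP90.1 passed in 1 and HSP70 in 0. Without control replicate 3 the list had adjusted p = 0.0555, without OBP4 replicate 1 0.0671, without the dimmest 50% of loci 0.0548, and by fry 0.113. None of 8 reference genes, used to scale measurements, passed by limma, also adjusted over the list alone; their median was -0.01, too close to 0 for a direction.

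**Figure D2:**
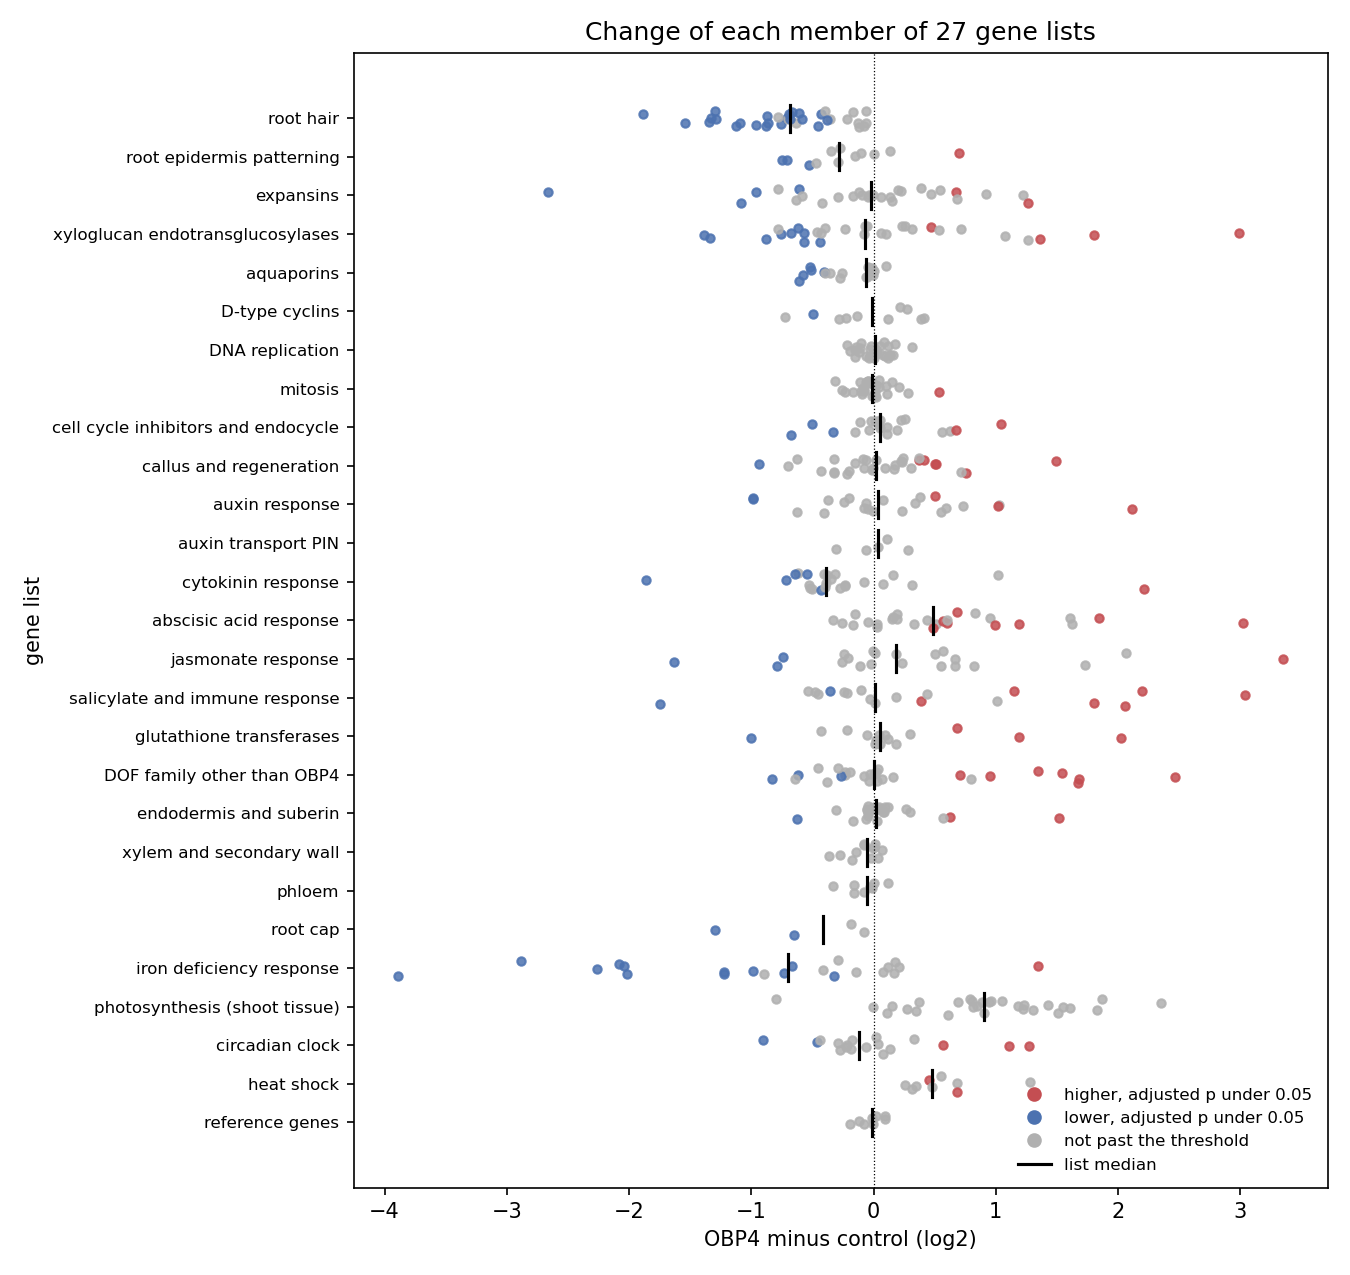
Difference between OBP4 and control roots on the log2 scale (horizontal axis) for each measured member of 27 gene lists (vertical axis), in red where higher and blue where lower at adjusted p under 0.05, in grey otherwise, with the list median as a black line. Root hair members lie at or below 0, with a median of -0.69 and 22 of 34 lower, while DNA replication members lie close to 0 with a median of 0.01.

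Photosynthesis genes, fixed as markers of shoot tissue, varied between arrays of the same group. The median of the 29 genes was 11.74, 11.42 and 12.84 in control replicates 1 to 3, and 15.35, 11.05 and 13.38 in OBP4 replicates 1 to 3. The list median difference was 0.90, with 0 of 29 genes past the threshold in limma, also adjusted over the list alone, and camera's adjusted p = 0.0906. The abscisic acid and heat shock counts above were measured in arrays that differ in this way, and so were all other lists.

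**Figure D3:**
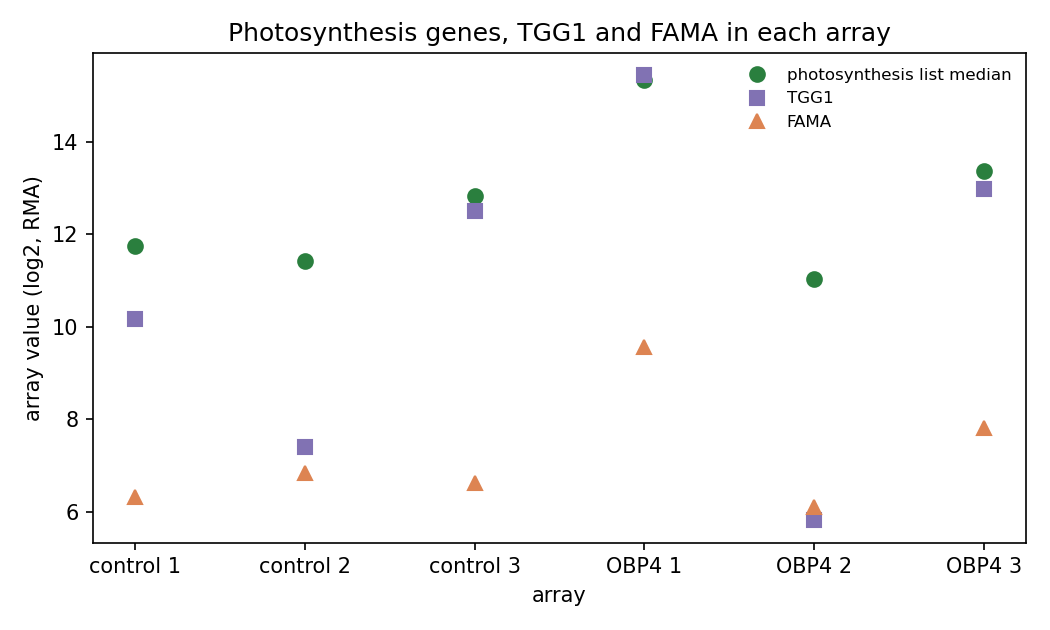
Array values on the log2 scale (vertical axis) in each of 6 arrays (horizontal axis) of the median of 29 photosynthesis genes (circles), TGG1 (squares) and FAMA (triangles). The list median runs from 11.05 in OBP4 replicate 2 to 15.35 in OBP4 replicate 1, and TGG1 from 5.82 to 15.44 in the same arrays.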

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

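All tests of this pattern were chosen after the result was seen. A signal lay in a second deposited table that carries the same sample names and on which no main result above rests. Under its own labels, limma called 1034 loci higher and 778 lower in OBP4 roots. In that table OBP4 itself stood at 13.95 ± 0.13 (SD, n = 3) under the control labels and 13.96 ± 0.04 (SD, n = 3) under the OBP4 labels, a difference of 0.01 ± 0.09 (SE) with limma's adjusted p = 0.98. Each of its 6 columns had a median of 11.84 and, to 2 decimals, the same quartiles; its scale appears to be log2, and what was done to normalize it is unknown. Levels across loci correlated with the own array at 0.968 to 0.983, so rows match, yet this is no closer than arrays of different groups are to each other (0.970 to 0.985).

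Explanations were weighed for why the table does not follow the arrays. If it held the same arrays normalized another way, deviations of each locus from its mean would be shared, but their correlation between a column and its own array had a median of 0.116, from -0.0792 to 0.214. Columns in another order are argued against by the highest of the 36 correlations between any column and any array, 0.463. Hybridizations of other RNA remain a possible explanation. By over 2 (log2), 393 loci differed between table and arrays under the control labels, and 636 under the OBP4 labels, against 351 between the 2 groups of arrays. The table's normalization is unknown, so these counts alone cannot tell other RNA from other processing. TT5, a flavonoid enzyme gene chosen after its values were seen, had a control mean of 15.40 in the arrays and 9.88 in the table, while its OBP4 means were 15.09 and 15.47. Of 590 loci called in both, 201 were higher and 226 lower in both, where independent lists would share 54.0 and 66.0. The other 163 had opposite signs: 37 were higher in the arrays and lower in the table, and 126 the reverse, where independent lists would give 40.7 and 87.7. No biological explanation was tested.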

How the results depend on the processing

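The covariate of the photosynthesis mean and the other locus for COG1 were chosen after seeing the data; all other settings were fixed before the data were examined. The OBP4 transcript kept its direction and stayed past the threshold in 16 settings, from 1.18 to 1.39 on the log2 scale with adjusted p from 5.91e-05 to 0.0277, and was 0.0067 (adjusted p = 0.98) in the second table. Camera with the preset correlation called 5 to 9 lists in 18 settings, and 0 with an estimated correlation. The estimate was 0.65 for root cap, 0.54 for heat shock, 0.46 for root hair and 0.21 for aquaporins. It was 0.18 for abscisic acid, 0.16 for iron and 0.03 for cytokinin, so all these called lists lie above the preset 0.01. Xyloglucan endotransglucosylases lay below the preset, at 0.006, yet camera's unadjusted p still rose from 0.136 to 0.193. It also rose for every other list with an estimate below the preset. The settings thus differ in more than the correlation, and how much of the loss of calls is due to correlation was not tested. Fry called 10 lists, adding root epidermis patterning, callus and regeneration, salicylate and DOF genes and losing heat shock. Without the dimmest 50% of loci, 33 named genes had no value and 48 of 81 were past the threshold. Quantile, median and loess scaling gave 63.1%, 58.4% and 60.1% of changed loci as lower, against 61.9%.

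Genes higher numbered 2561 with eBayes trend and robust, 669 at adjusted p under 0.01 and 560 with a change of at least 1; genes lower numbered 1295 and 999 in the last pair, which are stricter by construction. Leaving out single arrays gave 892 to 1309 genes higher, 1571 to 2048 lower, 5 to 8 lists, 62 to 68 named genes, 13 to 18 root hair members lower, 9 to 11 iron members lower and 3 to 9 abscisic acid members higher, with fewer samples in each fit. Of these 6 fits, 2 named genes (HSP70 and GH3.2) passed in 0, and 19 in at most 2. With the photosynthesis mean as a covariate 5 abscisic acid members were higher, and 17 root hair and 9 iron members were lower. In that fit 1608 genes were higher and 2174 lower, and 73 named genes were past the threshold. The covariate leaves fewer residual degrees of freedom by construction, and the cause was not tested.

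The labels do not say whether the same replicate number pairs arrays across the groups. Deviations of arrays with the same number correlated at -0.197, 0.093 and -0.17. These values show no strong shared variation but cannot exclude a weaker one. With the replicate block, 588 genes were higher and 1114 lower, 1665 of these 1702 being among the loci called without it; 10 root hair members were lower, 4 abscisic acid members higher and 53 named genes past the threshold, and residual degrees of freedom are fewer by construction. The root cap list had adjusted p = 0.0552 with the block, and the other 6 lists stayed past the threshold.

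The second table gave 1034 genes higher, 778 lower, 0 root hair members and 7 iron members lower, 0 abscisic acid members higher, and 15 named genes past the threshold with the same sign. With the opposite sign, 5 passed it: IDL3, NRT2:1, NCED3, ORA59 and CCA1. Fold changes across loci correlated with those of the arrays at 0.237. Of the 7 lists called in the arrays, root hair, iron and heat shock passed camera there, among 9 lists in all; aquaporins (adjusted p = 0.113), cytokinin (0.476) and root cap (0.676) did not, and the mean of the abscisic acid list reversed to -0.26 (0.314). Reversed signs, these 5 included, were seen for ORP4C (-0.12), IDL3 (-1.44), LCR26 (-0.15), QQS (0.16), NRT2:1 (0.93), IRT3 (0.29), MYC1 (-0.26), EXLA2 (0.33), PIP1;4 (0.022), CYCA2;3 (-0.043), KRP5 (-0.18), WOX12 (0.79), PLT5 (-0.05), ARF19 (-0.13), IAA5 (-0.16), LEA7 (-0.36), HAI2 (-0.56), NCED3 (-1.71), LOX4 (-0.013), ORA59 (1.13), JAZ6 (0.54), GSTU22 (0.037), CDF1 (-0.16), CDF5 (-0.76), BRN1 (0.06), NAS1 (0.023), CCA1 (-1.27), PRR9 (1.03) and RSL4 (0.16). The cause was not tested beyond the weighing given for this table.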

Other observations

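Other gene families stood out when all families of the array annotation and symbol stems with at least 15 members were scanned by Fisher's exact test across genes (520 tests, 34 past the threshold after Benjamini-Hochberg adjustment; genes are not independent replicates). The families named here were chosen after their values were seen. DC1 domain genes, which encode cysteine-rich zinc-binding domains, had the smallest p: 72 of 121 were lower and 3 higher, where 10.3 lower would be expected (adjusted p = 5.20e-43), with a median of -0.83 that stayed negative under each scaling. AT2G28270 fell by 3.37 and AT2G02620 by 2.93, and AT1G62030 rose by 1.62. Of 34 genes annotated with the exact phrase leucine-rich repeat protein kinase, 22 fell (adjusted p = 1.29e-13), AT3G46400 by 4.17. Kinase genes of this kind that are described in other words are not among the 34. Signal shared between neighbouring copies was not tested for them. Cytochrome P450 genes (60 of 240 lower) and disease resistance genes (38 of 117 lower) also fell more often than all loci, with adjusted p of 2.55e-12 and 2.02e-11.

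WRKY transcription factor genes changed in both directions: 20 of 67 rose (adjusted p = 1.17e-08) and 16 fell (adjusted p = 0.00376). WRKY71 (4.22), WRKY28 (4.13) and WRKY30 (2.58) rose, while WRKY61 (-1.94) and WRKY58 (-1.83) fell. Of 37 proton-dependent oligopeptide transport genes 15 fell (adjusted p = 9.31e-06), and NRT1.8, a nitrate transporter gene of this family, rose by 1.87. AT3G01345, without a symbol, had the value 15.48 ± 0.04 in control roots and 8.84 ± 1.66 in OBP4 roots (SD, n = 3), a change of -6.64 ± 0.82 (SE) with limma's adjusted p = 0.00624. Arrays without estradiol were not analysed here, so a difference between the 2 lines that precedes induction was not tested for this gene or any other.

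In the paragraphs that follow, the tests of neighbouring copies, of shoot markers and of scanning were set before their results were seen, and the tests of OBP4 induction, of the iron classes and of other splits after. Photosynthesis genes differed by a median of 2.84 (log2) between OBP4 replicates 1 and 2, and all 29 were higher in replicate 1. For an array-wide difference in scanning or normalization, 22766 loci in the same range of means differed by a median of -0.067. Normalization between arrays brings such a median near 0 by construction, so this test cannot decide on scanning. It shows only that no shift shared by these loci was left in the values. OBP4 induction stays open: the lowest OBP4 list median minus the lowest control median was -0.37, inside the spread of medians within a group (SD 0.74 in control and 2.15 in OBP4 arrays), and the other 2 OBP4 arrays lay above every control array. A varying share of shoot tissue is a candidate explanation too: 9 guard cell and shoot epidermis genes, listed before the test, differed by a median of 2.45 between these arrays. TGG1 differed most, at 15.44 against 5.82, while MUTE differed by 0.99, MYB60 by 0.73 and CER1 by 0.49. CER1 was at 11.69 or more in all 6 arrays and is no clean marker. The test compared OBP4 replicates 1 and 2 only.

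The fall of DC1 genes was tested against shared signal between tandem copies. Of 56 DC1 genes with no other DC1 gene among the 5 loci on either side, 31 (55.4%) fell, against 8.48% of all loci. This argues against signal shared between neighbouring copies as the whole cause. Signal shared with similar copies elsewhere in the genome was not tested. Without each array in turn, DC1 genes fell at least 8.56 times as often as all loci, and 60 to 67 of them were lower. The family was chosen because it fell in these same arrays, so this recount does not bear on whether OBP4 induction was the cause, and a difference between the lines apart from induction was not tested.

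The iron list was divided into genes that depend on FIT, the transcription factor for iron uptake, and the others, from general knowledge and after the values were seen. All 10 FIT-dependent genes fell, with a median of -2.03, while of the 12 others 2 fell and 1 rose, with a median of -0.03. The medians differed by -2.00. A two-sided permutation test over 100000 resamples of genes gave p = 0.00026, but the classes were assigned with the values in view, so this p decides nothing about the classes. The transcript of FIT itself fell by 1.22.

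With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4472 changed loci and was the 1 split with as many, the highest of the others giving 0. The 75 DC1 genes past the threshold in either direction, in 1 split, against 0 in the others, follow from those counts and add no separate evidence. For gene lists called by camera the real split gave 7, and 4 of the 10 splits gave as many, the highest of the others giving 8, so the number of lists does not set the real grouping apart.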
